A study of Mus musculus with 4 samples.

How the data were processed

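RNA was measured by sequencing in 4 libraries, 2 from normal mouse prostates and 2 from prostate tumours of TRAMP mice, which carry SV40 large T antigen under the rat probasin promoter. Per the labels, all animals were F1 males of C57BL/6 and FVB parents, the normal prostates were from mice of 22 weeks and the tumours from transgenic mice of 24 weeks, with 24 to 28 weeks per the labels' protocols. Tissue was dissected and frozen, total RNA was extracted with TRI Reagent, and libraries were made with a TruSeq RNA kit and sequenced on an Illumina NextSeq instrument, per the labels' protocols. The same protocols state that the tumours were large enough to give DNA for hydroxymethylation profiling too, while a normal prostate gave RNA or DNA only; no DNA data were analysed here. The labels do not say in words that the 2 tumours came from different mice, so p-values measure the spread between these samples. No sequencing batch is given.

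The authors deposited one Cufflinks gene table per library, with an FPKM value (fragments scaled by transcript length and by mapped fragments) and the bounds of its confidence interval for each gene. Trim Galore, TopHat2 2.0.8, Cufflinks 2.1.1, Cuffdiff 2.1.1 and the mouse build mm10 (GRCm38) are named per the submitters' processing notes. Trimming and alignment settings, the annotation and any scaling between libraries are not given in the sources used here. Each table held 24883 rows under 24344 gene names, the same rows in all 4, and 0 rows had a Cufflinks status other than OK. The 27 rows whose names had been turned into dates were left out, and the 817 rows of 280 names that occurred more than once were summed by name. Of 23284 gene names shared with GENCODE M21, 98.8% lay at an overlapping GRCm38 position. Positions are those of the deposited tables, counted from 1. Whether the counting used strand is not given in the sources used here, so a gene and a partner on the opposite strand cannot be told apart, and near-identical paralogs are uncertain.

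FPKM are not counts, and the deposited tables hold no counts. The fragments behind a value were estimated from the width of its Cufflinks interval, taken as 2 standard deviations of a Poisson count on each side. Among rows with a single transcription start group and 0.9 to 20 implied fragments, 71.0 to 72.5% lay within 0.1 of a whole number, against 20% by chance. Summed over all rows, the libraries held 986717 and 1580686 implied fragments for the normal prostates and 1435619 and 1143599 for the tumours. Intervals that also carry the uncertainty of assigning fragments to isoforms are wider than counting error, and the implied number is then too low. A gene may be listed at 0 because its estimate failed, so a value of 0 is given as listed at 0.

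All analyses from the FPKM on were made here, in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Each library was divided by its median-of-ratios factor over the 11469 genes listed above 0 in all 4 libraries. The factors were 0.793 and 0.689 for the normal prostates and 1.34 and 1.50 for the tumours, a shift of 0.94 on the log2 scale between the groups. Genes with a deposited FPKM of at least 1 in at least 2 of the 4 libraries were tested, 13162 in all, on log2(scaled FPKM + 1). The test was limma with an intensity trend, two-sided, tumour minus normal, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The residual degrees of freedom were 2 and the prior added 2.85. Fold changes are on the log2(scaled FPKM + 1) scale, which understates the change of low genes. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so none was used.

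The comparison, its test, 24 gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. The 12 lists of functions were TET and base excision, 2-oxoglutarate metabolism, DNA methylation, Polycomb, cell cycle, p53 targets, androgen response, prostate secretion, luminal epithelium, neuroendocrine, imprinted and germline. The 12 lists of cell types were basal epithelium, smooth muscle, fibroblast, endothelium, macrophage, T and NK cell, B and plasma cell, adipocyte, skeletal muscle, seminal vesicle, Schwann cell and red blood cell. The 20 lists with at least 3 genes tested were compared with all other genes by camera with a preset correlation of 0.01, adjusted over those 20 lists, and again with a correlation estimated per list and with fry. Members were also counted with p-values adjusted over the list alone.

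The rule named 43 genes, of which 1 is not reported here. It took Tet1, Tet2, Tet3, Dnmt1, Dnmt3a, Dnmt3b and Pbsn whatever their result, and the 5 largest rises and 5 largest falls among genes past the threshold. Those 10 also needed groups that did not overlap and a mean scaled FPKM of at least 5 in the higher group, and symbols ending in Rik or starting with Gm and a digit were left out. From each list of functions it took at most 2 members past the threshold in each direction by smallest p, at most 3 in all, or the member with the smallest p where none passed. From each list of cell types it took the member with the smallest p. Other members of the lists are given as examples chosen after their values were seen.

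The alternatives were FPKM as deposited, quantile normalization, a pseudocount of 0.1, no filter on low values, an FPKM of at least 5 in 2 libraries, no intensity trend, repeated names left out, rows of other status kept, each library left out in turn, a test against a log2 fold change of 1 and the other list tests. Scaling to the FPKM sum without genes above 1% of a library and limma voom on the implied fragments were added after the data were seen. The functions were tested on simulated libraries of 13538 genes for the comparison of tumour with normal, with a dispersion of 0.1 and 199 changed genes. The test recovered 44.0% of 4-fold and 99.0% of 16-fold changes, and 32 of its 174 calls (18.4%) were wrong, more than the threshold allows. In the same simulation camera gave a p of 1.5e-52 for a list of 20 changed genes and 0.304 for a list of 20 unchanged genes. Genes were drawn independently there, with the same dispersion in both groups. Correlations estimated for the real lists ran from -0.12 (red blood cell) to 0.83 (macrophage). The simulation therefore cannot check camera at the preset correlation, and its share of wrong calls need not hold in these data.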

Results

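The series asks how expression of the TET methylcytosine dioxygenases, which oxidise 5-methylcytosine to 5-hydroxymethylcytosine, differs between normal mouse prostate and prostate tumours of the TRAMP model. RNA-seq libraries of 2 normal prostates and 2 TRAMP tumours were compared. Implied depth was 986717 and 1580686 fragments in the normal libraries and 1435619 and 1143599 in the tumour libraries. An FPKM of at least 1 was reached by 11090 and 10763 genes in the normal prostates and by 12236 and 13863 genes in the tumours. Secretory transcripts held much of the FPKM of the normal libraries. Sbp, Sbpl and Spink1 together held 43.8% and 47.8% of all FPKM there, against 0.000338% in tumour 1 and 0.817% in tumour 2. FPKM are scaled by transcript length, so this is not a share of fragments. In normal 1 Spink1 held 176265 of 884622 FPKM but 51862 of 986717 implied fragments. Sbp and Sbpl are close paralogs whose separate values are uncertain. Values below are FPKM scaled to the median gene, with 2 libraries in each group, and SE is the standard error of the log2 fold change.

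Tumours and normal prostates differed widely. Among genes past the threshold that met the naming rule, the largest rises were those of Chga, Nnat, Peg10, Ddc and Birc5. Chga, the secretory granule protein chromogranin A (chromosome 12, 102554969 to 102565027), was listed at 0 in both normal prostates and lay at 133 and 396 in the tumours (adjusted p = 0.0195). Birc5, the mitotic protein survivin (chromosome 11, 117849237 to 117855743), rose by a log2 fold change of 7.17 (SE 0.44, adjusted p = 0.0187). Peg10, an imprinted retrotransposon-derived gene, rose by 7.31 (SE 0.89), a call that was lost by voom (10.66). Ddc, the aromatic amino acid decarboxylase, rose by 7.27 (SE 0.46) and overlaps a gene on the opposite strand. The largest falls under the same limits were those of Spink1, Pbsn, Tgm4, Mir29c and Wfdc3. Sbp (-11.76, adjusted p = 0.0609) and Defb50 (-10.22, adjusted p = 0.0812) fell further than Tgm4 but did not pass. Spink1, a secreted trypsin inhibitor (chromosome 18, 43728069 to 43737237), fell by 15.01 (SE 1.82, adjusted p = 0.0208). Tgm4, the prostate transglutaminase (chromosome 9, 123034741 to 123067558), fell by 10.01 (SE 0.30, adjusted p = 0.00705). Wfdc3, a whey acidic protein domain gene, fell by 9.09 (SE 0.66). Mir29c was listed at 0 in both tumours, and its normal values rested on 2.9 and 0.4 implied fragments. It overlaps A330023F24Rik on the same strand, and its call was lost by voom on the implied fragments (-2.16).

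Of 13162 genes tested with limma, 1296 were higher and 1088 lower in the tumours after Benjamini-Hochberg adjustment, so 54.4% of the called genes were higher. At an unadjusted p under 0.05 the counts were 2830 and 2412. Changes of at least 4-fold were found in 1010 of the higher and 657 of the lower genes. The groups did not overlap in 71.1% of genes tested, 4964 higher and 4389 lower, where chance gives 33.3% for a single gene. All genes share the same 4 libraries and are not independent, so the excess is no test of the groups. With FPKM as deposited the split was 3681 higher and 427 lower (89.6% higher), and scaled to the FPKM sum without genes above 1% of a library it was 2525 and 550 (82.1% higher). Without normal 1 or without normal 2, limma called 0 genes in either direction, while 1338 higher and 1096 lower, and 1350 higher and 1004 lower, had an unadjusted p under 0.05.

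The normal libraries resembled each other more than the tumours did. Across genes, which are not independent replicates, Pearson's r of the log2 values was 0.958 for the normal pair and 0.764 for the tumour pair. Tumour 1 had r of 0.468 and 0.473 with the normal prostates and tumour 2 had 0.703 and 0.709. The log2 difference between paired libraries had a standard deviation of 0.61 in the normal and 1.24 in the tumour pair. The first principal component held 80.2% of the variance, with both normal prostates at 1 end (-94.9 and -95.4), tumour 1 at the other (137) and tumour 2 between them, and the second held 14.9%.

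Of the TET genes, none passed the threshold over all genes tested. Tet1 (chromosome 10, 62804570 to 62880014) was low in normal prostate, at 0.203 in normal 1 and listed at 0 in normal 2, and lay at 4.16 and 1.499 in the tumours. Its log2 fold change was 1.71 (SE 0.48, adjusted p = 0.0679), a ratio of 3.27 on this scale. These values rested on 2.2 and 0 implied fragments in the normal prostates and 131 and 39.2 in the tumours. Tet3 (chromosome 6, 83362374 to 83441678) was at 3.22 and 2.71 in normal prostate and at 7.22 and 5.22 in the tumours, a log2 fold change of 0.85 (SE 0.41, adjusted p = 0.190). Tet2 (chromosome 3, 133463677 to 133544390) was at 2.80 and 1.83 against 3.13 and 3.30, a log2 fold change of 0.36 (SE 0.41, adjusted p = 0.540). All 3 genes were higher in both tumours than in both normal prostates, but of the 3 only Tet1 had an unadjusted p under 0.05. With FPKM as deposited Tet1 (log2 fold change 2.103, adjusted p = 0.0378) and Tet3 (1.61, adjusted p = 0.0432) passed and Tet2 (1.05, adjusted p = 0.115) did not. Over all alternatives run the adjusted p ranged from 0.0378 to 0.350 for Tet1, from 0.115 to 0.997 for Tet2, whose sign turned under quantile normalization (-0.0025), and from 0.0432 to 0.639 for Tet3.

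**Figure D1:**
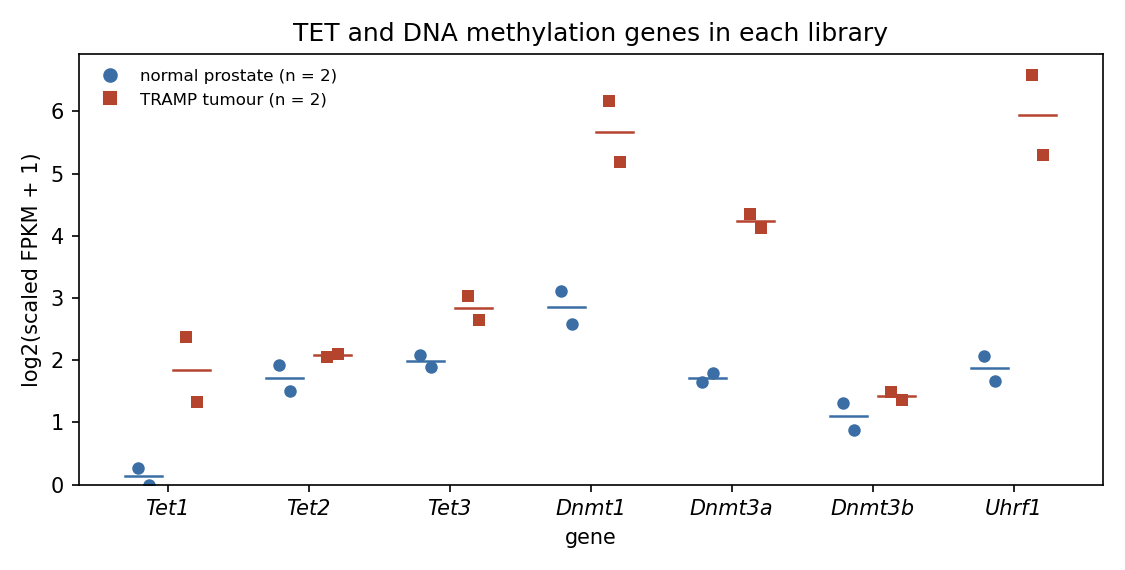
Expression of 7 genes in the 2 normal prostates (circles) and 2 TRAMP tumours (squares) as log2(scaled FPKM + 1), with a line at the mean of each group. Dnmt1, Dnmt3a and Uhrf1 passed the limma threshold, Tet1 (adjusted p = 0.0679), Tet2, Tet3 and Dnmt3b did not.

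In the list of TET and base excision genes, 1 of 17 tested members rose, 0 fell and 16 did not pass, while with FPKM as deposited 6 rose. The median log2 fold change was 0.83 over all 4 libraries. With 14 members tested it was 0.33 without tumour 1 and 1.08 without tumour 2. A lone tumour is assumed to vary as the normal prostates do. Counts without a tumour, here and below, therefore show only a distance from the normal pair and are no firmer support. Xrcc1, a scaffold of single-strand break repair, rose 3.06-fold (log2 fold change 1.62, SE 0.34, adjusted p = 0.0409), a call that was lost by voom, without the intensity trend and without the filter on low values. Tdg, the glycosylase that removes oxidised methylcytosine, lay at 0.000491 and 0.00032 in normal prostate and at 1.25 and 3.04 in the tumours, with an adjusted p of 0.0600. For Tet1 in normal 1, a value of 0.203 rested on 2.2 implied fragments. The normal values of Tdg lay far below that, so they are no measured level and cannot be told from 0. Adjusted over the list alone, 0 members passed, and camera did not call the list (adjusted p = 0.245). Of 18 genes of 2-oxoglutarate metabolism, which supplies the TET co-substrate, 1 rose and 17 did not pass, while with FPKM as deposited 8 rose and all 18 had a positive fold change, and without tumour 2 it was 3 higher and 1 lower. The call over all 4 libraries was Idh3a, a subunit of the mitochondrial NAD-dependent isocitrate dehydrogenase, at 4.02-fold (log2 fold change 2.01, SE 0.36, adjusted p = 0.0318), and it was lost without the filter on low values. Adjusted over the list alone 0 passed, and the camera adjusted p was 0.847.

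Among DNA methylation genes, Dnmt1, Dnmt3a, Uhrf1 and Hells rose, Mbd1 fell and Dnmt3b did not pass. Dnmt1, the maintenance methyltransferase (chromosome 9, 20907206 to 20959888), rose 7.09-fold from 7.65 and 5.01 to 71.1 and 35.2 (log2 fold change 2.83, SE 0.47, adjusted p = 0.0277). Dnmt3a, a de novo methyltransferase (chromosome 12, 3806980 to 3914443), rose 5.73-fold (2.52, SE 0.38, adjusted p = 0.0251) and overlaps the opposite-strand gene Dnmt3aos. Uhrf1, which recruits Dnmt1 to replicating DNA, rose 16.9-fold (4.08, SE 0.53, adjusted p = 0.0219), and Hells, a chromatin remodeller, rose 10.2-fold (3.35, SE 0.45). Dnmt3b (chromosome 2, 153649449 to 153687730) was at 1.49 and 0.839 against 1.81 and 1.55 (log2 fold change 0.33, SE 0.38, adjusted p = 0.557), with the opposite sign under quantile normalization (-0.19). Its values rested on 2.5 and 1.8 implied fragments in the normal prostates and 10.9 and 6.9 in the tumours, so its level is poorly measured. The methyl-CpG binding gene Mbd1 fell by 1.82 on the log2 scale (SE 0.32, adjusted p = 0.0307), a call that was lost with FPKM as deposited (-0.93). In all, 4 of 13 tested members rose, 1 fell and 8 did not pass, while adjusted over the list alone 5 rose and 2 fell. With FPKM as deposited 8 rose and 0 fell, and of 11 tested it was 3 and 2 without tumour 1 and 5 and 3 without tumour 2. The calls of Dnmt1, Dnmt3a, Hells and Mbd1 were lost without the filter on low values. The camera adjusted p was 0.163.

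Of 18 Polycomb genes (8 higher and 0 lower with FPKM as deposited, 4 and 2 without tumour 1, 8 and 2 without tumour 2), 1 rose, 1 fell and 16 did not pass, with the same counts adjusted over the list alone and a camera adjusted p of 0.325 (0.0239 without tumour 2, and 0.0239 to 0.816 over all alternatives run). Cbx2, a chromodomain subunit of Polycomb repressive complex 1, rose 7.52-fold (log2 fold change 2.91, SE 0.52, adjusted p = 0.0314), a call that was lost by voom (3.38) and without the filter on low values. Ring1, a ubiquitin ligase of that complex, fell by 2.78 (SE 0.53, adjusted p = 0.0347), a call that was lost with FPKM as deposited (-1.93) and without that filter. Ezh2, the H3K27 methyltransferase, lay at 6.49 and 1.81 in normal prostate and at 43.2 and 19.5 in the tumours (adjusted p = 0.0526).

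Imprinted genes were higher in the tumours. Of 14 tested members 7 rose, 1 fell and 6 did not pass, and adjusted over the list alone 8 rose and 1 fell. Nnat, which encodes neuronatin and lies inside Blcap on the opposite strand, rose by 7.77 (SE 0.83, adjusted p = 0.0195), and Ndn, which encodes the growth suppressor necdin, rose 26.6-fold (4.73, SE 0.45, adjusted p = 0.0195). Igf2r, the receptor that clears IGF2, fell by 2.76 (SE 0.57, adjusted p = 0.0398) and overlaps Airn on the opposite strand; this call was lost with FPKM as deposited (-1.90) and without the filter on low values. Of 8 members tested without tumour 1, 3 rose and 1 fell. The median log2 fold change was 2.48, or 2.37 without the 2 members listed at 0 in both normal prostates. Members that reached the filter through the 2 tumours alone remain in both values. With 1 tumour left out and 8 members tested, the median was 0.60 without tumour 1 and 1.95 without tumour 2. Camera called the list (adjusted p = 0.00236), with an adjusted p = 0.652 with an estimated correlation and 0.192 without tumour 1, when 8 members were tested, and a range of 0.000319 to 0.652 over all alternatives run.

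The cell cycle genes moved together. Of 34 tested members 31 rose, 0 fell and 3 did not pass, and adjusted over the list alone 33 rose. Besides Birc5, Mcm6, a subunit of the replicative helicase, rose 22.2-fold from 4.49 and 2.34 to 105 and 83.8 (log2 fold change 4.47, SE 0.39, adjusted p = 0.0195). Top2a, the mitotic topoisomerase, rose 63.4-fold (5.99, SE 0.54) and Mki67, the proliferation marker Ki-67, rose 26.7-fold (4.74, SE 0.56). The median log2 fold change was 3.95, or 3.82 without the 4 members listed at 0 in both normal prostates, at 4.45 in tumour 1 and 3.56 in tumour 2. Camera called the list (adjusted p = 1.41e-15), with an adjusted p = 0.652 with an estimated correlation. Of 21 p53 target genes 1 fell, 0 rose and 20 did not pass (0 fell and 1 rose with FPKM as deposited, 1 and 1 without tumour 1, 5 and 2 of 19 without tumour 2), 0 passed adjusted over the list alone, and the camera adjusted p was 0.366. The member that fell was Perp, a desmosomal gene, at 137 and 129 in normal prostate and at 0 and 10.9 in the tumours (log2 fold change -5.28, SE 1.18, adjusted p = 0.0446), and its call was lost with FPKM as deposited (-4.58), under quantile normalization (-4.89) and without the filter on low values. The median of the p53 targets was -0.18 and turned to 0.70 with FPKM as deposited.

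Neuroendocrine genes formed the other large group of rises. Of 24 tested members 19 rose, 0 fell and 5 did not pass, and adjusted over the list alone 22 rose. Scg5, which encodes the granule protein 7B2, was listed at 0 in both normal prostates and lay at 128 and 83.9 in the tumours (adjusted p = 0.0183). Syp, which encodes the vesicle protein synaptophysin, rose 26.8-fold (log2 fold change 4.74, SE 0.39, adjusted p = 0.0195). Foxa2 and Pcsk1 were listed at 0 in the normal prostates and tumour 1 and lay at 55.0 and 29.7 in tumour 2, too few libraries to be tested. The median log2 fold change was 4.56, or 3.44 without the 10 members listed at 0 in both normal prostates. With 1 tumour left out only 3 of the 24 members could be tested. Most members thus reached the filter through the 2 tumours alone, which favours a rise, and the value of 3.44 does not remove this. The median of the 3 was 4.32 without tumour 1 and 3.05 without tumour 2. Camera called the list (adjusted p = 3.2e-11), with an adjusted p = 0.652 with an estimated correlation. Without tumour 2, when 3 members were tested, the adjusted p was 0.0509, and it ranged from 1.58e-16 to 0.652 over all alternatives run.

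Prostate secretion genes were lower in the tumours, while luminal genes differed between tumour 1 and tumour 2. Of 12 tested prostate secretion genes 2 fell, 0 rose and 10 did not pass, and 6 fell adjusted over the list alone. The 2 were Tgm4 and Spink1. Without tumour 1 the fold change was negative in 10 of the 12 members and positive in 2, and without tumour 2 it was negative in all 12. The median log2 fold change was -6.50, at -9.12 in tumour 1 and -3.48 in tumour 2, and camera called the list (adjusted p = 0.000557), with an adjusted p = 0.652 with an estimated correlation. Of 17 luminal epithelium genes 1 fell, 0 rose and 16 did not pass, and 0 passed adjusted over the list alone. Without tumour 1 it was 9 lower and 3 higher, and without tumour 2 it was 16 and 1. Spdef, an ETS factor of secretory epithelium, lay at 181 and 225 in normal prostate and at 0 and 11.7 in the tumours (log2 fold change -5.83, SE 1.21, adjusted p = 0.0398), a call lost with FPKM as deposited (-5.12) and without the filter on low values. Krt8, a luminal keratin, lay at 178 and 191 in normal prostate, at 0.258 in tumour 1 and at 438 in tumour 2 (adjusted p = 0.451). The luminal median was -3.29, at -6.05 in tumour 1 and -0.92 in tumour 2. Camera called the luminal list (adjusted p = 0.00654), with an adjusted p = 0.652 with an estimated correlation and 0.215 without tumour 1, and a range of 1.48e-09 to 0.652 over all alternatives run.

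Genes of the androgen response went both ways. Of 18 members 2 rose, 3 fell and 13 did not pass (4 and 3 with FPKM as deposited, 1 and 7 without tumour 1, 2 and 11 without tumour 2), and adjusted over the list alone 2 rose and 4 fell. Fkbp5, a co-chaperone of steroid receptors, fell by 4.64 (SE 0.26, adjusted p = 0.0183) from 493 and 653 to 21.9 and 21.7. Pbsn, which encodes probasin and whose rat promoter drives the transgene (chromosome X, 77837898 to 77853500), fell by 10.73 (SE 1.28, adjusted p = 0.0204). Ndrg1, a stress-response gene, rose 5.17-fold (log2 fold change 2.37, SE 0.40, adjusted p = 0.0282), a call that was lost without the filter on low values. Camera did not call the list (adjusted p = 0.0827), but did with FPKM as deposited (0.00482) and under quantile normalization (0.0413), with the FPKM sum without genes above 1% of a library (0.0158) and with each library left out in turn (0.000846 to 0.0192), in a range of 0.000846 to 0.652 over all alternatives run.

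**Figure D2:**
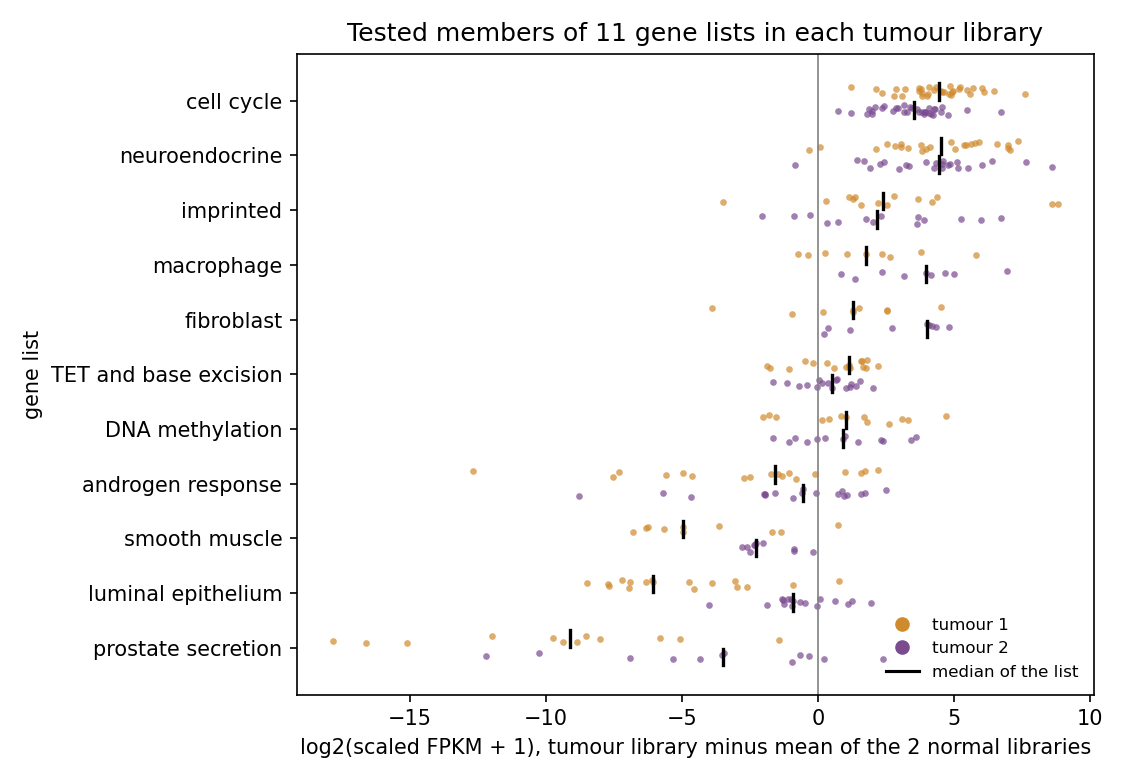
Each point is 1 tested member of a gene list in 1 tumour library, as log2(scaled FPKM + 1) minus the mean of the 2 normal libraries, for 11 lists, with a black bar at the median of the list. The luminal epithelium median lies at -6.05 in tumour 1 and -0.92 in tumour 2, while the cell cycle medians lie at 4.45 and 3.56.

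Markers of other cell types differed between the groups too. Smooth muscle genes were lower: of 10 members 2 fell, 0 rose and 8 did not pass, with 9 lower adjusted over the list alone and a median of -3.63. Without tumour 1 it was 7 lower and without tumour 2 it was 8. Synm, a muscle intermediate filament gene, fell by 3.05 (SE 0.54, adjusted p = 0.0312), a call lost by voom (-5.43) and without the filter on low values, and camera called the list (adjusted p = 0.00236), with an adjusted p = 0.652 with an estimated correlation. Macrophage genes were higher, with 4 of 9 members up, 0 down and 5 that did not pass, 5 up adjusted over the list alone, and a camera adjusted p of 0.00641 (adjusted p = 0.652 with an estimated correlation). Lyz2, the macrophage lysozyme, rose 83.3-fold (log2 fold change 6.38, SE 0.68, adjusted p = 0.0195). The rise was not shared evenly, since Csf1r (0.31, adjusted p = 0.798) and Adgre1 (0.24, adjusted p = 0.776) hardly moved. In tumour 1, 7 of the 9 members lay above both normal prostates and 2 below both. Of 9 fibroblast genes 2 rose, 0 fell and 7 did not pass, with the same counts adjusted over the list alone and 4 higher with FPKM as deposited, while of 5 tested without a tumour 3 rose (without tumour 1) or 2 rose and 2 fell (without tumour 2). Fbln1, an extracellular matrix gene, rose 20.7-fold (4.37, SE 0.42, adjusted p = 0.0195), and the camera adjusted p was 0.0470 (adjusted p = 0.652 with an estimated correlation). Of 4 red blood cell genes 3 rose and 1 did not pass, with the same counts adjusted over the list alone and a camera adjusted p of 0.00998 (adjusted p = 0.652 with an estimated correlation). That call was also lost with repeated names left out (0.0695) and with no filter on low values (0.163), in a range of 0.000275 to 0.652. Hba-a1, an alpha globin gene on 2 rows with near-identical copies, rose 20.2-fold (4.34, SE 0.32, adjusted p = 0.0195).

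The macrophage median was 1.76 in tumour 1 and 3.97 in tumour 2, and that of fibroblasts 1.31 and 4.01. With FPKM as deposited the camera adjusted p was 0.183 for fibroblasts and 0.0569 for macrophages. For fibroblasts it was 0.967 without tumour 2, 0.125 with the FPKM sum without genes above 1% of a library and 0.0530 with repeated names left out. Over all alternatives run it ranged from 0.00044 to 0.967 for fibroblasts and from 1.28e-06 to 0.652 for macrophages.

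The remaining lists were not called by camera. Of 8 basal epithelium genes 1 fell, also adjusted over the list alone, and 7 did not pass (camera adjusted p = 0.133, but 0.0486 with FPKM as deposited, in a range of 0.0231 to 0.652). Without tumour 1 it was 3 lower and 1 higher, and without tumour 2 it was 5 lower. The 1 call was Krt5, a basal keratin, which fell by 3.46 (SE 0.74, adjusted p = 0.0414), a call lost with FPKM as deposited (-2.83), by voom (-5.20) and without the filter on low values. Of 3 adipocyte genes 1 fell, also adjusted over the list alone, and 2 did not pass (0.284). It was Plin4, a lipid droplet gene that overlaps Hdgfrp2, which fell by 2.25 (SE 0.39, adjusted p = 0.0302), a call lost without that filter. None of 5 endothelium genes (0.510), 4 skeletal muscle genes (0.993) and 6 Schwann cell genes (0.971) passed, over all genes or adjusted over the list alone. Without tumour 1 they had 2, 1 and 1 higher and 0, 1 and 0 lower, and without tumour 2 they had 1, 0 and 1 higher and 0, 1 and 1 lower. Their members with the smallest p were Egfl7 (adjusted p = 0.0685), Acta1 (0.0922) and Pmp22 (0.0505), and Egfl7 and Pmp22 passed with FPKM as deposited (2.41 and 2.66). The skeletal muscle median was 0.01 while its mean was -0.17 and camera's direction was down, and the Schwann cell median was 0.05 with a mean of -0.03. In the T and NK cell list 1 gene was tested, Lck, listed at 0 in the normal prostates and at 2.87 and 2.08 in the tumours (adjusted p = 0.0352). These values rested on 10.7 and 5.8 implied fragments, and the call was lost under quantile normalization (1.30), without the filter on low values and by voom (3.35). In the germline list 1 gene was tested, Brdt (log2 fold change 0.85, adjusted p = 0.182). In the B and plasma cell list 0 genes were tested, and the 7 seminal vesicle genes were listed at 0 in all 4 libraries.

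Of the 20 lists tested by camera, 6 were called higher and 3 lower, and 0 were called with an estimated correlation. That setting also uses the 2 residual degrees of freedom, which alone raises p. The imprinted list (estimated correlation -0.046) went from an unadjusted camera p of 0.000589 to 0.0674. Red blood cell (-0.124) went from 0.00399 to 0.0999, though both correlations lay below the preset 0.01. The shared adjusted p of 0.652 covers unadjusted p from 0.0388 (neuroendocrine) to 0.489 (androgen response). By fry, which tests each list on its own, 3 were called, all higher: neuroendocrine (adjusted p = 0.0336), imprinted (0.0361) and red blood cell (0.0361).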

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

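The scaling to the FPKM sum without genes above 1% of a library and the voom fit were chosen after the data were seen. With FPKM as deposited 3681 genes were higher and 427 lower, and with the FPKM sum without genes above 1% of a library 2525 and 550. All 1296 genes called higher were shared with both of these, and of the 1088 called lower 426 and 550 were shared. Without a filter on low values 245 genes were higher and 249 lower among 17072 tested, and tested against a log2 fold change of 1 there were 180 and 102. Leaving out each library in turn gave 0 to 2170 higher and 0 to 3405 lower genes. The 0 counts came without either normal prostate, where the lone normal is assumed to vary as the tumours do, and the large ones without a tumour (1304 and 2251 without tumour 1, 2170 and 3405 without tumour 2). With only 1 tumour left, that tumour is assumed to vary as the normal prostates do. The log2 difference had a standard deviation of 0.61 in the normal pair and 1.24 in the tumour pair. The larger counts without a tumour are therefore no firmer support. A gene below an FPKM of 1 in both normal prostates cannot reach the filter with 1 tumour, so fewer genes of that kind are tested. Quantile normalization, a pseudocount of 0.1, an FPKM of at least 5, no intensity trend, repeated names left out and voom (1017 and 960, of which 917 and 837 shared) kept both counts within 1.5 times. Keeping rows of other status moved nothing, since all rows had the status OK.

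With FPKM as deposited Tet1 (2.103) and Tet3 (1.61) passed the threshold; Tet2 (-0.0025) and Dnmt3b (-0.19) changed sign under quantile normalization. The cause was not tested. Tet1 was not tested without either tumour or at an FPKM of at least 5, nor was Tet2 at that filter. With an estimated correlation, on 2 residual degrees of freedom, 0 lists were higher and 0 lower, and by fry 3 and 0. As deposited, FPKM gave 4 lists higher and 5 lower, and with the FPKM sum without genes above 1% of a library 5 and 5. The red blood cell list was not called with repeated names left out (adjusted p = 0.0695) or with no filter (0.163), in a range of 0.000275 to 0.652. For the named genes other than the TET genes, 409 of 531 values kept direction and side of the threshold, 109 were no longer past it (66 of them without a normal prostate, 16 without the filter on low values), 12 came to pass it and 1 reversed, that of Dnmt3b. Of the 109 lost calls, 6 were lost with a pseudocount of 0.1 and 4 with the FPKM sum without genes above 1% of a library. Neither these nor the losses without a normal prostate are named gene by gene in the Results. Without the intensity trend 2 were lost, of which only that of Xrcc1 is named. The settings listed beside a gene are therefore not complete. No paired analysis was possible because the labels pair no normal prostate with a tumour. Tet1 had 2.2 and 0 implied fragments in the normal prostates. By voom the calls of Mir29c (-2.16), Lck (3.35), Xrcc1 (1.62), Cbx2 (3.38), Peg10 (10.66), Synm (-5.43) and Krt5 (-5.20) were lost, and the cause was not tested. In the simulation, with independent genes and equal dispersion in both groups, 18.4% of calls were wrong. The share in these data is not known, and a single call near the threshold is weak evidence.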

Other observations

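Genes of groups outside the fixed lists were looked at after the data were seen, in 6 lists written then, and all the tests of explanations below were chosen after the results were seen. The 12 genes listed for the neuronal cytoskeleton and synapse all rose and passed the limma threshold, with a median log2 fold change of 4.99. Since the list was written after the data were seen, this count is no test of that gene group. Stmn1, a tubulin regulator, rose 74.3-fold and Basp1, a growth cone protein gene, 47.0-fold. Of 14 glycolysis genes 8 rose, 0 fell and 6 did not pass, with Gapdh 4.50-fold and Pkm 3.09-fold higher. Cdkn2a, which encodes p16 and p19Arf, was listed at 0 in both normal prostates and lay at 88.7 and 72.4 in the tumours (adjusted p = 0.0183). Trp53 rose 3.11-fold (limma adjusted p = 0.0439) and Rb1 2.84-fold (0.0498). Myc fell by 1.77 on the log2 scale (0.0495), a call that was lost with FPKM as deposited (-0.94). The calls of Trp53, Rb1 and Myc all lay just under the threshold. Of 25 ribosomal protein genes 14 fell and 11 did not pass, with a median of -1.06. With FPKM as deposited the median was -0.11, 4 fell and 0 rose. The size of the fall and the number of calls thus rest on the scaling. The sign of the median did not turn, while that of single members such as Rps3 (0.62 as deposited) did.

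MHC class I genes were lower in tumour 1 than in tumour 2. Of 8 tested members 1 fell (Tapbp, a call that was lost with FPKM as deposited, -2.29) and 7 did not pass, with a median log2 fold change of -2.92, and tumour 2 lay above tumour 1 by a median of 2.98. B2m, the shared light chain, lay at 40.9 in tumour 1 and 1038 in tumour 2. The genes Hoxb4 to Hoxb9 lay higher in tumour 2, by a median log2 difference of 6.05, with Hoxb8 listed at 0 in tumour 1 and at 107 in tumour 2. None of these 6 genes passed the threshold between tumours and normal prostates. A difference between 2 single libraries has no replicate check.

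The tumours differed from each other in epithelial genes, and genes of smooth muscle (2.64), fibroblasts (2.55) and macrophages (2.02) were higher in tumour 2 too by the median log2 difference, while those of the cell cycle (-0.99), imprinted genes (-0.71), Polycomb (-0.58), neuroendocrine genes (-0.56) and the neuronal cytoskeleton (-1.46) were lower there. Of the genes tested 980 were at least 4-fold higher in tumour 2 and 186 in tumour 1, while 124 were as far apart in the normal pair. In the luminal list 16 of 17 genes were higher in tumour 2, by a median log2 difference of 4.51 between single libraries; the deposited FPKM of Krt8 were 0.346 and 658, and Cdh1, E-cadherin, was listed at 0 and at 59.1. Normal prostate of the kind in the normal libraries, mixed into tumour 2, is argued against as the whole cause. The evidence is abundant normal genes that were far below normal in tumour 1. Ribosomal genes and Rik symbols were left out, and the 10 most abundant others, such as Spink1 and Pbsn, were taken. In tumour 1 the highest of the 10, Mt1, lay at 0.952% of its normal level. In tumour 2 the 10 lay at a median of 1.12% (quartiles 0.218 and 6.41) and the luminal genes at 52.4% (41.6 and 107). A shallower library of tumour 1 is argued against too, since the luminal genes at the level of tumour 2 would give a median of 217 fragments there (39.6 to 2992), and the median seen was 1. What stays open, and was not tested, is that tumour 1 may hold little luminal epithelium, or a difference in stage between the mice. Another mixed tissue stays open too. It includes normal prostate with low levels of secretory genes such as Spink1 and Pbsn, which the 10 genes cannot show.

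As deposited, the median gene was higher in the tumours by 0.86 on the log2 scale. After the 7 genes above 1% of a library were left out of the FPKM sum the median was still 0.62 (95% bootstrap interval over genes 0.59 to 0.64). In these 4 libraries those few genes alone therefore do not account for it. Too few fragments for low genes in the normal libraries is argued against as the whole cause. Among the 3644 genes with a mean FPKM of at least 20 the median was 0.63 (0.58 to 0.69). Both intervals come from resampling genes, not libraries, so they leave out the spread between libraries. A wider set of abundant normal genes may contribute and was not tested. FPKM are scaled by mapped fragments, so they cannot show a difference in total RNA per cell.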
